A study of Mus musculus with 2 samples.

How the data were processed

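The study measured RNA in single brain endothelial cells of mice 22 months old after ALPL, the tissue-nonspecific alkaline phosphatase, was inhibited with a drug or after vehicle. Per the labels' protocols, cortex and hippocampus were dissociated with a Neural Dissociation Kit, cells were taken by flow cytometry, and 10x Genomics v3 libraries were made, each from a pool of 4 mice. There were 2 libraries, 1 per group, so a group had n = 1, the mice within a pool could not be told apart, and no replicate error existed. Groups were taken from the sample titles. The deposited file names carry the opposite condition: the files of the sample titled vehicle are named for Alpl, and those of the sample titled ALPL are named for vehicle. Which of the labels is right was not given in the sources used here, and no value was used to settle it. The text therefore speaks of the library labelled vehicle and the library labelled ALPL, and every direction relative to the treatment stays open.

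The deposited values were whole-number UMI counts per gene and barcode with no normalization, as a raw matrix of every barcode and a filtered matrix of barcodes called as cells. Per the file headers the counts came from software version 3.1.0, whereas per the submitters' processing notes Cell Ranger 3.0.0 was run on the mouse build mm10. The aligner settings and the annotation release were not given in the sources used here. The filtered counts were checked against the raw matrices and were equal for every shared barcode. Of the 31053 gene identifiers, 30934 (99.6%) were found in GENCODE M21, from which the gene positions (GRCm38, the assembly of mm10) were taken. There were 35 symbols that each named more than 1 identifier, and such genes were kept apart by identifier. Reads shared by near-identical genes such as Hspa1a and Hspa1b, or H2-Q6 and H2-Q7, could be split between them by the counting, so their single values are uncertain.

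The raw matrix of the library labelled vehicle held 21222244 UMIs in 469817 barcodes, of which 4250 barcodes with 19043542 UMIs (89.7%) were called as cells. The library labelled ALPL held 23694093 UMIs in 490600 barcodes, of which 5281 barcodes with 21438595 UMIs (90.5%) were called as cells. Cells with at least 500 genes and at most 15% of UMIs from mitochondrially encoded genes were kept, which removed 63 and 40 barcodes. Doublets were called per library with Scrublet as implemented in scanpy, at an expected rate of 0.05, and removed. Scrublet called 1 of the 9531 barcodes (0.0105%), under the 0.5% taken as the least share of a working call, so doublets were in effect not removed, and an alternative left out the cells with the highest 5% of UMIs. The kept cells numbered 4186 and 5241, with medians of 4372.5 and 3934 UMIs and of 2073 and 1913 genes per cell.

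Counts per cell were scaled to 10000, log-transformed, and reduced to 30 principal components of 2000 variable genes chosen across both libraries, leaving out every member of the fixed gene lists. Leiden clusters were found at resolution 1.0 on a graph of 15 nearest neighbours, without integration of the libraries, and endothelial-like cells were clustered again at resolution 0.6. Clusters were called X-like from 16 type marker lists and, within endothelium, 3 segment marker lists (arterial, capillary, venous). The marker lists were fixed before the data were examined, but the score was revised after clusters had been seen. It used the share of cells with a UMI for cell types and geometric means for segments. A cluster stayed unnamed where under 3 markers were detected in at least 10% of its cells, where genes of another class led it, or where its cells were shallow, with a median under 1/3 of the library's UMIs per cell, and no own marker was among its 10 leading genes. The cluster left unnamed for depth lay just under this bound, at 0.332, and a cluster of 26 cells at 0.369 kept the endothelial name without a leading marker. The unnamed cells made up 5.85% of the library labelled vehicle and 4.87% of the library labelled ALPL. A sub-cluster led by Plvap had no segment name and stayed in the endothelial-like class.

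UMIs were summed per library over all endothelial-like cells and over each segment, and divided by the sum's total to give CPM. The ratio always sets the library labelled ALPL over the library labelled vehicle. CPM values carry exact Poisson intervals, ratios exact conditional binomial intervals and shares of cells exact Clopper-Pearson intervals, each at 95%. These intervals cover counting error only: they hold no variation between mice, pools or preparations. With 1 library per group no test was run, and no p-value, standard error or count of changed genes was made. No fold was given where both libraries held 3 or fewer UMIs. Each of 28 gene lists was described by the median log2 ratio of its members with a mean of at least 10 CPM, by how many members were at least 1.25-fold higher or lower (called the preset fold bound), and by the median's percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries.

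The lists covered phosphate and mineralisation, receptors of receptor-mediated transcytosis, clathrin machinery, caveolae and vesicles of non-selective uptake, tight and adherens junctions, nutrient transporters of the barrier, ABC efflux transporters, iron handling, canonical Wnt signalling, type I interferon response, antigen presentation, and endothelial inflammation and leukocyte adhesion. They also covered immediate early genes, heat shock, unfolded protein and integrated stress response, hypoxia and glycolysis, cholesterol synthesis, BMP and TGF-beta response, VEGF response and tip cells, Notch response, shear stress response, basement membrane, senescence and DNA damage, lysosome and autophagy, cell cycle, mitochondrially encoded genes, cytosolic ribosomal proteins and the nuclear-encoded respiratory chain. A further 4 lists (interferon-gamma response, glucocorticoid response, and circadian output with and without Dbp) were drawn up for hypotheses after the data had been seen.

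Named genes followed a rule fixed before the data were examined. They were the 12 highest and 12 lowest ratios in endothelial-like cells among genes with a mean of at least 50 CPM, leaving out mitochondrially encoded, ribosomal protein and haemoglobin genes and unnamed gene models. Alpl, Tfrc, Plvap, Cav1, Mfsd2a, Cldn5, Slc2a1 and Abcb1a were named whatever their values, as were the 2 highest and 2 lowest members of each list from 20 CPM and, in each segment, the 5 highest and 5 lowest genes. Of the left-out genes, 1 lay above the lowest of the 12 highest and 0 below the highest of the 12 lowest.

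The ratio and list steps were tested on simulated counts drawn from the means and totals of the endothelial-like sums. The draws were independent Poisson counts, the model that the intervals assume, without variation between cells, mice or libraries. They therefore check the computation only. Among 3421 unchanged genes the interval held the true value for 96.0%, and 0% lay beyond 1.25-fold. Of 50 genes made 1.25-fold different 52% lay beyond that bound, as did 100% of the 50 made 1.5-fold different. Of 200 simulated lists without an effect, 5% fell outside the middle 95% of random lists, and a list changed 1.5-fold gave a median of 0.60 at percentile 100.

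The alternatives tried were a strict cell filter (1000 genes, 10% mitochondrial UMIs), no cell filter, doublets kept, edgeR's TMM scaling, a median-of-ratios scaling, each cell weighted equally, each cell thinned to 2000 UMIs, and sub-clusters weighted equally in both libraries. In the last, a sub-cluster had the same weight in both libraries, the mean of its shares of their endothelial-like cells. Sub-clusters thus did not weigh the same as each other. Free RNA was subtracted with the profile of droplets of 1 to 50 UMIs; its share was set by few marker classes, 1 in the library labelled vehicle (4.58%) and 2 in the library labelled ALPL (12.9%, between 0.917% and 24.9%), so it is a weak estimate. Other minimums for list members (none, 50 CPM) and named genes (20 CPM), clustering at resolutions 0.5 and 2.0 and sub-clustering at 0.3 and 1.2 were also tried. Chosen after seeing the data were leaving out the Plvap-led sub-cluster, keeping only sub-clusters with at least 20% of their cells from each library, leaving out the highest 5% of UMIs, and clustering the libraries separately. Python 3.11.15 was used with scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and edgeR 4.0.16 was used in R 4.3.3.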

Results

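Single-cell RNA was measured in endothelial cells sorted from cortex and hippocampus of mice 22 months old, in 1 library labelled vehicle and 1 labelled ALPL, each a pool of 4 mice. The library labelled vehicle gave 4186 kept cells with a median of 4372.5 UMIs, and the library labelled ALPL gave 5241 with a median of 3934. Cells ranged from 735 to 29059 UMIs in the first and from 797 to 27958 in the second. The deposited file names carry the opposite condition to the sample titles, so "labelled ALPL" and "labelled vehicle" follow the titles, and the direction relative to the inhibitor is open throughout. There are no replicates: intervals give counting error only, and each ratio compares 2 libraries, not the conditions. Doublets were in effect not removed, since the caller marked 1 cell.

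Almost all cells were endothelial-like in both libraries. Endothelial-like cells, defined by markers such as Cdh5 and Pecam1, made up 93.6% (interval 92.8% to 94.3%, 3917 cells) of the library labelled vehicle and 94.7% (94.1% to 95.3%, 4965 cells) of the library labelled ALPL. Pericyte-like cells, the mural cells of capillaries, numbered 24 (0.573%, 0.368% to 0.852%) and 21 (0.401%, 0.248% to 0.612%). The flow sort for endothelium can set these shares. A shallow cluster without a name held 228 and 234 cells. Inside the endothelial-like sums, markers of microglia stood at 32.7 and 31.1 CPM, of astrocytes at 36.9 and 32.4 CPM and of pericytes at 53.4 and 57.8 CPM. Neutrophil markers reached 4 and 10 UMIs. Erythrocyte markers stood at 67.6 CPM in the library labelled vehicle and 5.04 CPM in the library labelled ALPL, and 4 cells held 1098 of the 1238 UMIs in the former. No class other than endothelium reached 100 cells per library, so ratios in other cell classes have no value.

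The series asks how brain endothelium responds when ALPL is inhibited, so Alpl comes first. Alpl (ENSMUSG00000028766, chromosome 4, 137741733 to 137796384, mm10) encodes tissue-nonspecific alkaline phosphatase. In endothelial-like cells it stood at 210 CPM (204 to 217, 3850 UMIs) in the library labelled vehicle and 119 CPM (114 to 124, 2479 UMIs) in the library labelled ALPL. The ratio was 0.565 (0.537 to 0.595), a log2 ratio of -0.82 (-0.90 to -0.75). The transcript was most abundant in arterial-like cells, with 369 and 250 CPM, against 111 and 64.3 CPM in capillary-like cells. An inhibitor of the enzyme acts on the protein, so this transcript does not show which library had the drug. Among sub-clusters shared by both libraries the log2 ratio was -0.40.

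Across endothelial-like cells, the 12 genes with the highest ratios of the library labelled ALPL over the library labelled vehicle included Lcn2, Cebpd, Osmr, Socs3 and Vcam1, and the 12 with the lowest included Plvap, Tfrc, Gbp4, Igtp and Irgm1. Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), an acute-phase protein that binds bacterial siderophores, stood at 15.8 CPM in the library labelled vehicle and 269.6 CPM in the library labelled ALPL, a ratio of 17.0 (15.1 to 19.2). Cebpd (ENSMUSG00000071637, chromosome 16, 15887286 to 15891031), a transcription factor of the acute-phase response, held 1464 and 9539 UMIs, a ratio of 5.72 (5.41 to 6.05). The cytokine-response genes Osmr, a subunit of the oncostatin M receptor, and Socs3, a feedback inhibitor of JAK-STAT signalling, had ratios of 2.49 (2.33 to 2.67) and 2.11 (1.92 to 2.33). Vcam1 (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688), to which leukocytes attach, stood at 52.5 and 116 CPM. Cdkn1a, the cyclin-dependent kinase inhibitor p21, stood at 248 and 708 CPM. Tmem252 reached a log2 ratio of 2.27, Scgb3a1, a secreted secretoglobin, 1.95, Acer2, an alkaline ceramidase, 1.24, and Ier3 1.22. Fam107a had a log2 ratio of 1.14 and the death receptor Fas 1.13. All 12 of these genes were also higher in the library labelled ALPL within arterial-like, capillary-like and venous-like cells, although arterial-like Lcn2 rested on 3 and 44 UMIs.

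The lowest ratio was that of Plvap (ENSMUSG00000034845, chromosome 8, 71497765 to 71511752), which forms the diaphragms of fenestrae and caveolae: 122 CPM in the library labelled vehicle and 12.5 CPM in the library labelled ALPL, a log2 ratio of -3.28. A sub-cluster of 118 and 19 cells held 2199 of the 2230 and 252 of the 261 Plvap UMIs, and within it Plvap stood at 4581 and 3561 CPM. The barrier gene Cldn5 was low there, at 596 and 692 CPM, against 6711 and 5504 CPM over the class. Tfrc (ENSMUSG00000022797, chromosome 16, 32608920 to 32632794), the transferrin receptor of the barrier, stood at 431 and 224 CPM, a ratio of 0.520 (0.501 to 0.539). The interferon-inducible GTPases Gbp4, Igtp and Irgm1 had log2 ratios of -1.69, -1.09 and -0.86, and H2-Q7, a class I histocompatibility gene with near-identical copies, -0.89. Gkn3, an arterial gene of brain vessels, stood at 217 and 72.6 CPM. The immediate early transcription factors Egr1 and Nr4a1 had log2 ratios of -1.36 and -0.84, the clock output factor Dbp -0.97 and the fatty acid desaturase Scd2 -0.84. With sub-clusters weighted equally Igtp was -0.67, Irgm1 -0.38 and Dbp -0.56, and in shared sub-clusters Nr4a1 was -0.40 and Scd2 -0.44. In every segment 10 of these 12 genes, Alpl included, were lower in the library labelled ALPL; Egr1 and Nr4a1 were higher in venous-like cells, where Plvap rested on 2 and 0 UMIs.

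Further genes of the barrier were named whatever their values. Slc2a1, the glucose transporter of the barrier, stood at 1668 CPM in the library labelled vehicle and 2426 CPM in the library labelled ALPL, a ratio of 1.45 (1.43 to 1.48). Cldn5, its main tight junction claudin, stood at 6711 and 5504 CPM, a ratio of 0.820. Cav1, the caveolar coat protein, stood at 339 and 234 CPM, a ratio of 0.692 (0.666 to 0.719). Mfsd2a, a lipid transporter that restrains transcytosis, stood at 180 and 192 CPM, and the efflux pump Abcb1a at 1397 and 1303 CPM. Among 3621 genes with a mean of at least 50 CPM the SD of the log2 ratio was 0.24, and 89.6% of genes lay within the preset fold bound. In sub-clusters shared by both libraries Mfsd2a turned to -0.01, and the log2 ratio of Plvap was -1.31, of Gkn3 -0.94 and of H2-Q7 -0.28. There that of Slc2a1 was 0.36. With sub-clusters weighted equally that of Scgb3a1 was 0.92, of Acer2 0.80, of Fas 0.73, of Cav1 -0.32 and of Plvap -0.38.

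**Figure D1:**
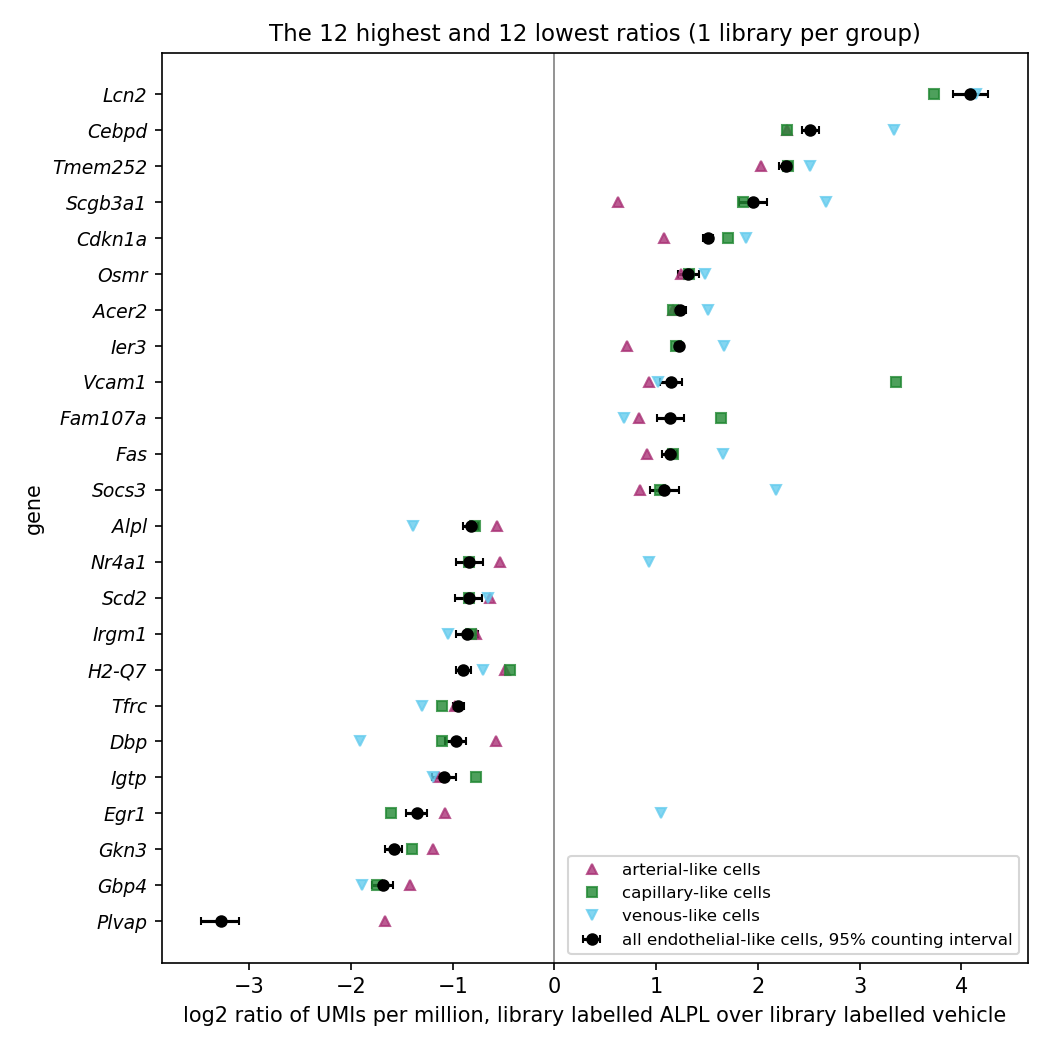
Log2 ratios of CPM, library labelled ALPL over library labelled vehicle (horizontal axis), for the 12 highest and 12 lowest genes (vertical axis). Black points with bars are all endothelial-like cells with their 95% counting intervals, coloured symbols are the segments, drawn where each library held over 3 UMIs, and 1 library stands for each group. Lcn2 lies at 4.09 and Plvap at -3.28, and Egr1 and Nr4a1 have venous-like points on the other side of 0.

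Of the gene lists, endothelial inflammation and leukocyte adhesion stood highest, with 8 of 13 measured members higher in the library labelled ALPL by at least the preset fold bound, 1 lower and 4 between. Its median log2 ratio was 1.04, at percentile 100 of random lists; it was 0.66 with each cell thinned, 0.67 without a minimum expression and 0.56 with sub-clusters weighted equally. Beside Lcn2, it held Ch25h, the cholesterol 25-hydroxylase, at 8.63 and 55.5 CPM, whereas Cx3cl1, a membrane-bound chemokine, had a log2 ratio of -0.44 and Icam2 -0.17. Ch25h is also a venous marker, and venous-like cells made up 6.03% and 5.40% of the class. Heat shock genes had 6 of 12 members higher and 0 lower, a median of 0.33 and percentile 100; the near-identical chaperone genes Hspa1b and Hspa1a stood at 0.98 and 0.75, Hspb1 at 0.07 and Bag3 at 0.02. Immediate early genes were split, with 8 of 19 higher, led by Ier3 and Atf3 (0.98), and 5 lower, led by Egr1 and Nr4a1, around a median of 0.20 at percentile 100 that was 0.03 with sub-clusters weighted equally. Hypoxia and glycolysis had 3 of 16 higher and 1 lower, a median of 0.19 at percentile 99.99, with the vasodilator peptide Adm at 1.04, the mitophagy receptor Bnip3 at 0.71, and the glycolytic enzyme Eno1 at -0.33; its median was 0.09 with sub-clusters weighted equally.

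Antigen presentation stood lowest of the lists: 12 of 13 members were lower in the library labelled ALPL by the same bound and 0 higher, with a median of -0.55 at percentile 0. The immunoproteasome subunit Psmb9 stood at 171 and 105.5 CPM and the class I heavy chain H2-D1 at 1564 and 1184 CPM, while the peptide-loading protein Tapbp had a log2 ratio of -0.19. Without the Plvap-led sub-cluster, among whose leading genes is Cd74, 9 of 11 members were lower and the median was -0.46, and in shared sub-clusters 6 of 12 were lower and the median was -0.28. Canonical Wnt signalling in brain endothelium had 6 of 17 members lower and 1 higher, a median of -0.29 at percentile 0. Its target Tnfrsf19 stood at 147 and 104 CPM and the Wnt deacylase Notum had a log2 ratio of -0.41, whereas the receptor Fzd4 stood at 0.33. The type I interferon list had 1 of 20 members lower and 0 higher, with Ifi44 at 0.28, a median of -0.07 at percentile 2.93. Its direction turned among shared sub-clusters, with a median of 0.38 and 11 members higher, and with sub-clusters weighted equally, with 0.32.

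For routes across the barrier, receptors of receptor-mediated transcytosis went both ways, with 3 of 13 members higher, 4 lower, and a median of -0.06 at percentile 12.5; in shared sub-clusters it was -0.10 at percentile 1.62, beyond the middle 95%. Insr, the insulin receptor, had a log2 ratio of 0.58, against -0.94 for Tfrc and -0.37 for Fcgrt, the neonatal Fc receptor. Caveolae and vesicles of non-selective uptake had 6 of 12 members lower and 1 higher, a median of -0.23 at percentile 0, with Plvap and Cav1 lowest, Flot1 at 0.48 and Cavin2 at 0.14. Without the Plvap-led sub-cluster that median was -0.03 (11 members, percentile 28.0), and in shared sub-clusters it was 0.02. All 20 clathrin machinery genes lay within the bound, from Epn2 at -0.24 to Rab11a at 0.17, with a median of -0.03 (percentile 23.7) that became 0.01 and 0.02 because TMM and median-of-ratios scaling add a constant 0.039 and 0.047 to every log2 ratio. Tight and adherens junctions had 3 of 15 members lower and 1 higher, a median of -0.11 at percentile 1.09, with Ctnnb1 at -0.40 and the connexin Gjc1 at 0.33. Nutrient transporters of the barrier had 1 of 19 lower and 1 higher (median -0.14, percentile 0.24), with the iron exporter Slc40a1 at -0.65, the taurine transporter Slc6a6 at -0.30 and Slc1a1 at 0.29. All 7 ABC efflux transporters lay within the bound, with Abca1 at -0.29, Abcc4 at 0.15 and a median of -0.09 (percentile 12.5) that was 0.06 without the Plvap-led sub-cluster.

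Phosphate and mineralisation, the list that holds Alpl, had 2 of 11 members lower and 1 higher, a median of -0.15 at percentile 1.73 that was -0.29 in shared sub-clusters. Mgp, an inhibitor of calcification rich in arterial-like cells, stood at 520 and 855 CPM, Gas6 had a log2 ratio of -0.51 and the phosphate exporter Xpr1 0.04. Iron handling had 3 of 8 members higher and 1 lower, a median of 0.12 at percentile 97.6, with the ferritin chain Fth1 at 0.43 and the ferroxidase Cp at 0.42. In shared sub-clusters its median was 0.05 at percentile 83.2, within the middle 95% of random lists, and with sub-clusters weighted equally it was 0.01. BMP and TGF-beta response had 3 of 14 higher and 1 lower (median 0.10, percentile 98.7, or 96.3 with the highest 5% of UMIs left out, and 91.4, 93.3 and 92.0 within arterial-like, capillary-like and venous-like cells), with the inhibitory Smad7 at 0.63, Smad6 at 0.33 and Tgfb1 at -0.21. Cytosolic ribosomal proteins had 1 of 76 higher, Rps6 at 0.38, and a median of 0.09 at percentile 99.9. The 13 mitochondrially encoded genes all lay within the bound, led by mt-Nd1 at -0.23, with a median of -0.15 at percentile 0.64 that was -0.34 with free RNA subtracted. Basement membrane genes had 0 of 13 beyond the bound, with the proteoglycan Hspg2 at -0.31, Fn1 at 0.16 and a median of -0.10 (percentile 3.11, or 2.45 in shared sub-clusters).

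The remaining lists had medians within the middle 95% of random lists over the whole class. VEGF response and tip cells had 2 of 9 members higher and 2 lower, with Nrp2 at -0.69 and Angpt2 at 0.32; its median was 0.08 (percentile 91.6), its mean was -0.04, and its median turned to -0.22 without a minimum expression but was 0.25 (percentile 99.97) without the Plvap-led sub-cluster. Cholesterol synthesis had 0 of 12 members beyond the bound, Msmo1 at 0.30 and a median of 0.08 (percentile 97.3). Notch response had 1 of 9 higher, the target Hey1 at 0.50, and a median of 0.05 (percentile 82.7). Unfolded protein and integrated stress response had 1 of 13 higher, the transcription factor Xbp1 at 0.82, with the chaperone Calr at -0.24 and a median of 0.04 (percentile 83.9) that was 0.12 (percentile 99.67) in shared sub-clusters. Shear stress response had 3 of 9 higher, with S1pr1 at 0.42 and Klf2 at 0.38, and 1 lower, the vasoconstrictor Edn1 at -0.62; its median of 0.04 (percentile 70.6) turned to -0.03 with sub-clusters weighted equally, whereas in shared sub-clusters it was 0.18 (percentile 99.95, 4 members higher and 0 lower). Within arterial-like, capillary-like and venous-like cells the shear stress median was 0.28, 0.19 and 0.31, at percentiles 99.99, 99.55 and 99.43. Senescence and DNA damage had Cdkn1a higher and Trp53 (-0.34) lower among 9, with Btg2 at -0.30; its median of 0.02 (percentile 64.9) turned to -0.19 among members from 50 CPM. Lysosome and autophagy had 1 of 14 higher, a median of -0.00 (percentile 52.0) that the constant of TMM and median-of-ratios scaling brought to 0.04 and 0.05, Sqstm1 at -0.30 and Lamp2 at 0.18. Of 75 nuclear-encoded respiratory chain genes 0 lay beyond the bound, with Uqcrh at 0.19 and a median of -0.02 (percentile 11.1) that the same constants brought to 0.02 and 0.03. Of the cell cycle list 3 members were measured, 0 beyond the bound, with Stmn1 at -0.26, Pcna at -0.09 and a median of -0.09 (percentile 29.6). Of the lists beyond the middle 95% over the class, some lay within it in single segments: immediate early genes, caveolae, junctions, iron handling and phosphate in arterial-like cells (percentiles 85.6, 40.0, 7.14, 34.5 and 4.84), caveolae and iron handling in capillary-like cells (80.7 and 95.9), and phosphate and ribosomal proteins in venous-like cells (13.6 and 97.0). Within single segments, medians also lay beyond the middle 95% for VEGF response (0.24), Notch response (0.14) and basement membrane (-0.11) in arterial-like cells, the respiratory chain (-0.05) in capillary-like cells, cholesterol synthesis (0.25) in venous-like cells, and the unfolded protein response in arterial-like (0.11) and venous-like cells (0.27). The type I interferon list did so in arterial-like (0.12), capillary-like (-0.11) and venous-like cells (-0.41).

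**Figure D2:**
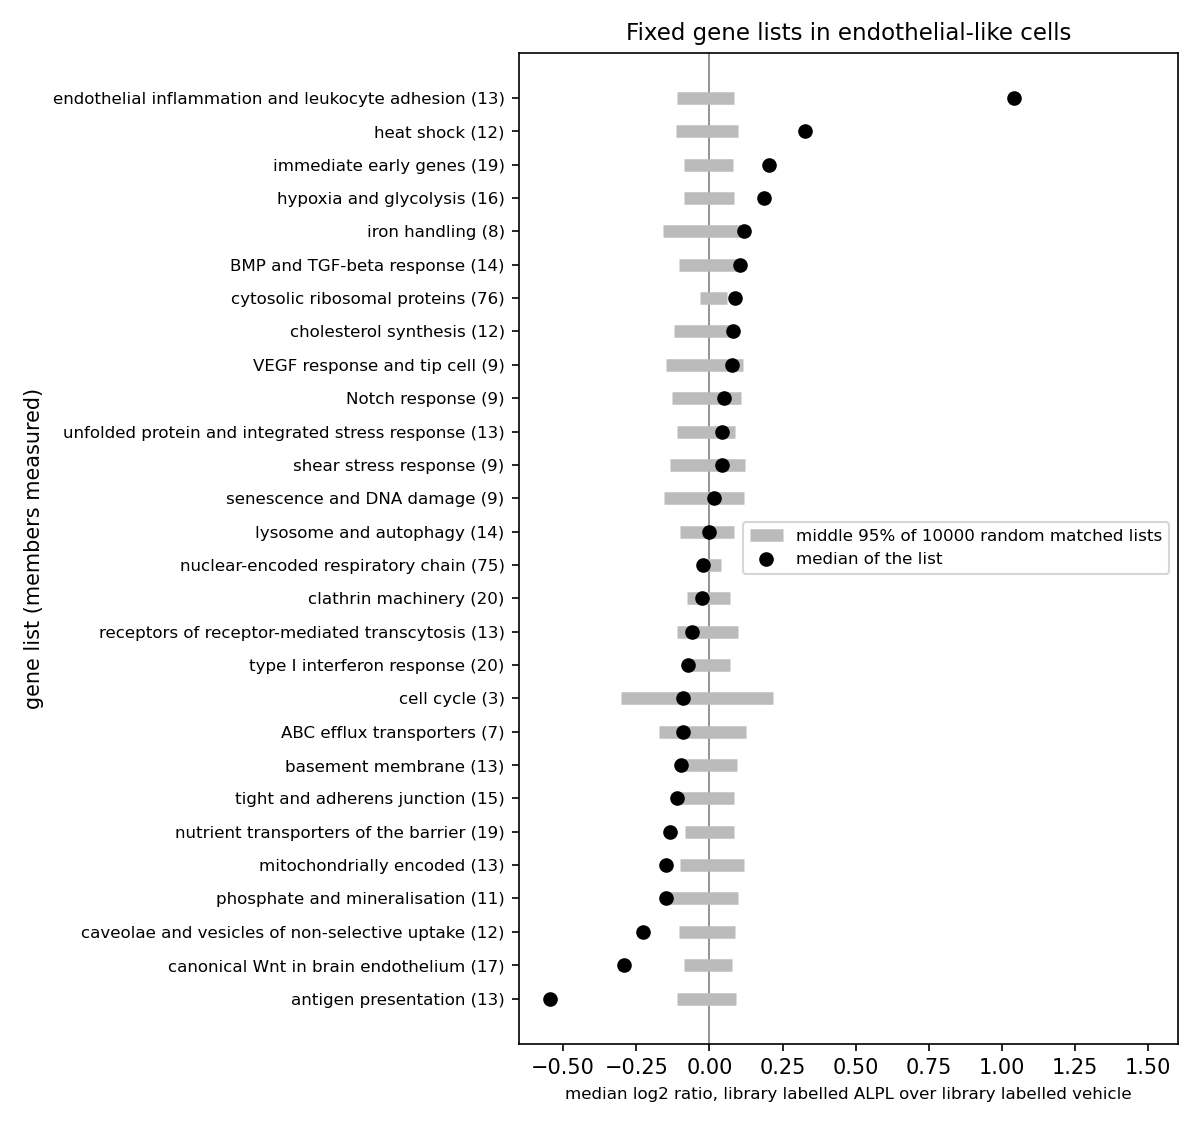
Median log2 ratio, library labelled ALPL over library labelled vehicle (horizontal axis), of each fixed gene list in endothelial-like cells (vertical axis, with the number of members measured). Points are list medians and grey bars the middle 95% of 10000 random lists matched on expression. Endothelial inflammation and leukocyte adhesion lies at 1.04, antigen presentation at -0.55, and the medians of clathrin machinery, lysosome and autophagy, and the respiratory chain lie at -0.03, -0.00 and -0.02, so close to 0 that the constant added by TMM or median-of-ratios scaling makes them positive.

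Brain endothelium is zoned along the vessel, and ratios within arterial-like, capillary-like and venous-like cells ask whether the differences hold inside each zone. Tfrc was lower in the library labelled ALPL in each, with log2 ratios of -0.98, -1.11 and -1.30 in that order, as was Alpl, with -0.56, -0.78 and -1.39 (33 and 14 UMIs in venous-like cells). The size for Alpl depended on how the segments were drawn: over the alternatives it ran from -1.002 to -0.34 in arterial-like, from -1.17 to -0.27 in capillary-like and from -2.78 to -0.92 in venous-like cells. Cebpd had log2 ratios of 2.29, 2.28 and 3.34. Lcn2 was concentrated in venous-like cells, at 199 and 3511 CPM, against 6.13 and 81.5 CPM in capillary-like and 0.399 and 6.74 CPM in arterial-like cells. Free RNA held Lcn2 too, at 21.9 and 259 CPM in droplets of 1 to 50 UMIs, so a part of its low levels in capillary-like and arterial-like cells is not told from it. Vcam1 stood at 498 and 1008 CPM in venous-like and 4.16 and 42.7 CPM in capillary-like cells. Slc2a1 was higher in the library labelled ALPL in each segment (0.37, 0.58 and 0.62), Cldn5 lower (-0.35, -0.34 and -0.33) and Cav1 lower (-0.44, -0.50 and -1.08). In the capillary-like sub-cluster that both libraries shared, Slc2a1 was 0.25, Cldn5 -0.20, Cav1 -0.30, Alpl -0.32 and Tfrc -0.74, and in the other, with 49 cells labelled vehicle, Cav1 was 0.12. Mfsd2a went from 0.24 in arterial-like to -0.10 in capillary-like and -0.49 in venous-like cells, and Abcb1a lay at -0.16, -0.14 and -0.24. Both arterial-like sub-clusters gave higher values for Mfsd2a than their sum, 0.32 and 1.36. In the capillary-like sub-clusters Mfsd2a was 0.03 (shared) and -0.09.

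The genes with the highest ratios in arterial-like cells were Cebpd, Tmem252 (2.03), Osmr (1.24), Acer2 (1.17) and Cdkn1a (1.08), and the lowest were Gbp4 (-1.42), Gkn3 (-1.19), Igtp (-1.14), Egr1 (-1.08) and Tfrc. In capillary-like cells the highest were Mgp, at 6.78 and 93.5 CPM, Tmem252 (2.29), Cebpd, Scgb3a1 (1.85) and Cdkn1a (1.71). Mgp stood at 1239 and 2365 CPM in arterial-like cells, so arterial cells or free RNA within the capillary-like sums are not told from a difference in capillary cells. Among the lowest there were Gbp4 (-1.75), Egr1 (-1.60), Tfrc and Dbp (-1.11). Venous-like sums held 1155631 and 1287505 UMIs, against at least 6527931 in the other segments, so counting error alone widens their ratios. The highest there included Serpina3n, an acute-phase serine protease inhibitor, at 6.92 and 134 CPM, Ifitm1, an interferon-induced membrane protein, at 27.7 and 320 CPM, and the venous markers Ackr1 and Lrg1 at log2 ratios of 5.87 and 3.84. The lowest venous-like ratios were Unc13c (-2.31), Dbp (-1.92), Gbp4 (-1.89), Cyp2e1, a cytochrome P450 (-1.88), and Lmntd1 (-1.75). Endothelial inflammation and leukocyte adhesion had medians of 0.27, 1.04 and 1.02 in arterial-like, capillary-like and venous-like cells, antigen presentation -0.40, -0.39 and -0.40, and canonical Wnt signalling -0.26, -0.30 and -0.31. Within the preset fold bound lay 91.9% of genes in arterial-like, 88.5% in capillary-like and 69.9% in venous-like cells, shares that cannot be compared between segments of unequal totals.

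Different sub-clusters held most of the capillary-like cells: 1 held 2081 of the 2130 cells labelled vehicle, and another, led by Cebpd and Cdkn1a, held 2028 of the 3310 cells labelled ALPL and 49 labelled vehicle, and may be that library, not a type. Venous-like cells parted too: at sub-cluster resolution 1.2, 1 venous-like sub-cluster held 541 and 160 cells and another, led by Lcn2 and Lrg1, held 5 and 204, so whether the venous-like ratios of Lcn2, Vcam1, Ackr1 and Lrg1 compare like cells is open. At that resolution an arterial-like sub-cluster led by Tmem252 and Mgp held 28 and 836 cells. Arterial-like cells numbered 1433 and 1368 and venous-like cells 236 and 268; Tfrc in venous-like cells turned to 0.20 at sub-cluster resolution 0.3, and Alpl there was -2.78 with the libraries clustered separately. The 12 highest-ratio genes together had medians of 6 and 10 UMIs per arterial-like, 5 and 14 per capillary-like and 8 and 37.5 per venous-like cell at full depth. With each cell thinned to 2000 UMIs, which 3828 of 3917 and 4798 of 4965 endothelial-like cells reached, they were 2 and 4, 2 and 7, and 3 and 17.

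**Figure D3:**
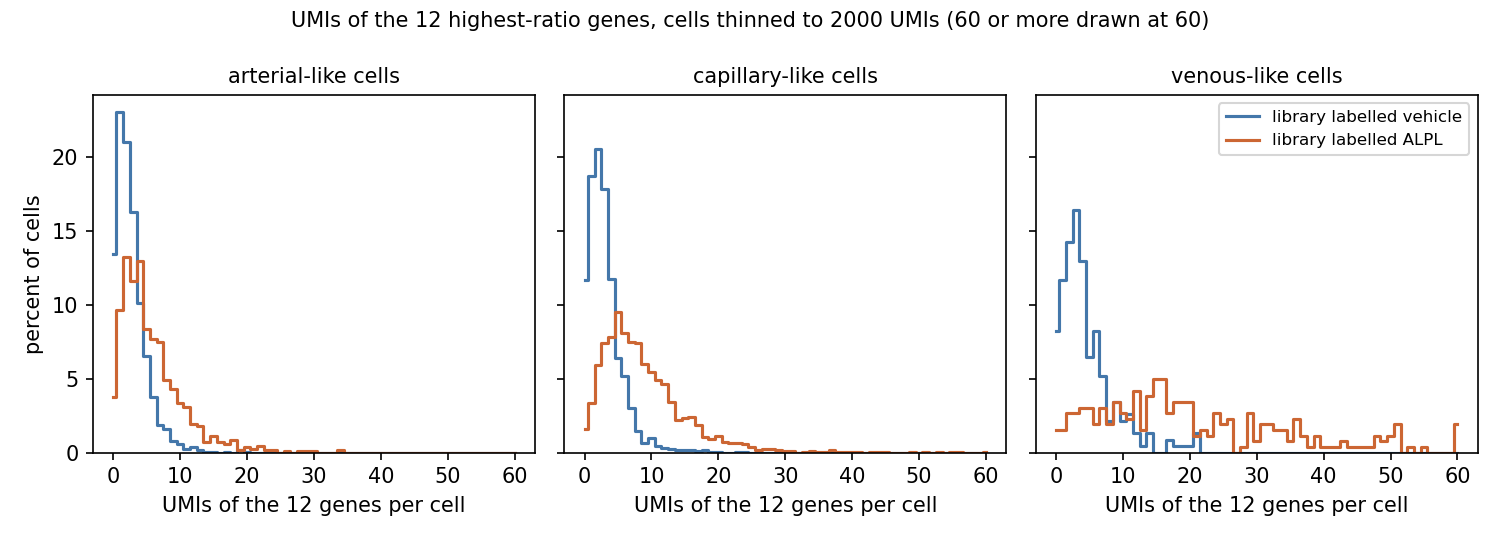
Percent of cells (vertical axis) by the number of UMIs of the 12 highest-ratio genes per cell (horizontal axis), in arterial-like, capillary-like and venous-like cells thinned to 2000 UMIs, with blue for the library labelled vehicle and orange for the library labelled ALPL. The medians were 2 and 4 UMIs in arterial-like, 2 and 7 in capillary-like and 3 and 17 in venous-like cells, for genes chosen because they differed.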

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

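The tests of leukocytes, venous share, affected mice, Plvap-led cells, mix of segments and depth below were chosen after the results they examine had been seen. Every direction follows the sample titles, which the file names contradict.

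The acute-phase genes Lcn2 and Cebpd and the adhesion gene Vcam1 were among the 12 genes with the highest ratios in the library labelled ALPL. Leukocytes among the endothelial-like cells are argued against, since the CPM of 5 neutrophil markers together differed by 0.103% of the difference in Lcn2, B cell markers held 16 and 14 UMIs and T or NK cell markers 0 and 2. A larger share of venous cells with the mean levels of the library labelled vehicle is argued against for 11 of the 12 genes. These stood higher over all endothelial-like cells labelled ALPL than in venous-like cells labelled vehicle that were clustered without the other library. Cebpd, for example, stood at 458 and 103 CPM. Of these, Cdkn1a, Acer2, Fas, Fam107a and Socs3 stood above that level over the class labelled vehicle already. Their place among the 11 was thus fixed, and only the others could have come out differently. More cells of a particular venous-like kind stay open, since the level is a mean. At sub-cluster resolution 1.2 a venous-like sub-cluster led by Lcn2 and Lrg1 held 5 and 204 cells. Vcam1 stood at 37.3% of the mean venous-like level, so this comparison cannot decide for it. Venous-like cells were 6.03% and 5.40% of the class, or 10.1% and 4.31% with the libraries clustered separately. Neither clustering thus gave the library labelled ALPL the larger venous share that this explanation needs. At sub-cluster resolution 0.3 the cluster named venous-like held 28 and 2142 cells. It was led by Cebpd and Tmem252, which are not among the venous markers, so its count is a poor measure of a venous share. That only 3 or fewer of the 4 pooled mice differed stays open. In the library labelled ALPL 4.94% of capillary-like and 13.4% of arterial-like cells lay below the vehicle library's median for the 12 genes, but this decides nothing: the genes were chosen for their difference, several of them lead a sub-cluster and so shape the segments, and free RNA, in which Lcn2 and Cebpd differed too, would raise the score of any unaffected mouse's cells. Treatment, pool, dissociation and library preparation cannot be told apart with 1 library per group, and a biological response to the inhibitor is 1 of the open explanations.

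Plvap was lower in the library labelled ALPL. Fewer cells of the Plvap-led sub-cluster may account for most of this: the sub-cluster held 98.6% of the Plvap UMIs of the library labelled vehicle, and within it the log2 ratio was -0.36. In the other endothelial-like cells, with 31 and 9 Plvap UMIs, the ratio was 0.249 (0.104 to 0.536), and the cause of that was not tested. Barrier transcripts were low in this sub-cluster. Cldn5 stood there at 596 and 692 CPM, against 7313 and 6371 in the capillary-like sub-cluster shared by both libraries. Slc2a1 stood at 106 and 353 CPM, against 1667 and 1982. The Plvap ratio over the class thus mostly reflects cells with little of the barrier's transcripts, and which vessels they came from was not tested. Whether the 118 and 19 cells differ by treatment, by dissection or by the sort was not tested.

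Alpl and Tfrc were lower in the library labelled ALPL. A different mix of segments is argued against as the whole cause, since with sub-clusters weighted equally in both libraries the higher of the log2 ratios of both genes was -0.62. This weighting leans on a capillary-like sub-cluster with 49 cells labelled vehicle, but little on the Plvap-led one with 19 cells labelled ALPL. For Alpl the mix may account for a part, since arterial-like cells, where it was most abundant, were 36.6% and 27.6% of the class. In shared sub-clusters Alpl was -0.40, against -0.82 over the class, and Tfrc -0.99, against -0.94. That set cannot decide this, because leaving out a capillary-like sub-cluster with cells mostly labelled ALPL changes the mix again. Within the shared capillary-like, both arterial-like and the venous-like sub-clusters Alpl was -0.32, -0.49, -0.83 and -1.39. Tfrc was -0.74, -0.77, -0.31 and -1.30 in the same order. Thinning each cell to 2000 UMIs gave -0.81 for the higher of both log2 ratios, but it cannot decide whether lower depth per cell matters. CPM already divides by the total, and random thinning keeps each gene's expected share of a cell, so it mainly changes the weight of each cell. A difference between the pools or preparations, and one made by the treatment, stay open.

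Egr1 had a log2 ratio of 1.05 (0.41 to 1.72; 30 and 69 UMIs) in venous-like cells against -1.08 in arterial-like and -1.60 in capillary-like cells, and stood out because the segments went opposite ways; the difference was not tested, and with the libraries clustered separately the venous-like value was 1.13. Nr4a1 had 0.93 in venous-like cells (-0.36 to 2.35; 8 and 17 UMIs) against -0.54 and -0.84 in arterial-like and capillary-like cells, a difference also not tested and within counting error of 0 in venous-like cells. In droplets of 1 to 50 UMIs, outside the cells compared, Lcn2 stood at 21.9 and 259 CPM, a ratio of 11.85 (8.15 to 17.8), and Cebpd at 57.7 and 388 CPM, a ratio of 6.73 (5.30 to 8.64). Among cells without a class, 1 cell of the library labelled ALPL held 1149 UMIs of Ttr, the main transcript of choroid plexus epithelium, against 3 UMIs in the 245 unnamed cells of the library labelled vehicle.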

How the results depend on the processing

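Leaving out the Plvap-led sub-cluster, keeping shared sub-clusters, leaving out the highest 5% of UMIs and clustering the libraries separately were chosen after the data had been seen; the other alternatives were planned. No paired analysis was possible because each group has 1 library and no test was run, and for the same reason no replicate could be left out. No other cell class had enough cells for a value. Of the values that answer a comparison, 68 stayed within their counting interval or, for the count of named genes, within 1.5 times, 30 moved beyond it and 1 reversed. Of the named genes' values, 252 stayed and 84 moved, 83 of these with the same sign; of the other list medians 300 stayed, 288 with the same sign, and 62 moved, 45 with the same sign. Alpl ranged from -0.85 to -0.40 and Tfrc from -0.99 to -0.80 in endothelial-like cells. TMM and median-of-ratios scaling shifted all log2 ratios by 0.039 and 0.047.

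With the strict cell filter the endothelial-like shares were 98.2% (vehicle) and 98.9% (ALPL), and the log2 ratio of Alpl was -0.72 in arterial-like and -0.92 in capillary-like cells and of Tfrc -1.03 in capillary-like cells. Without a cell filter Alpl was -0.34 in arterial-like and Tfrc -1.19 in capillary-like cells. With the 1 called doublet kept, Alpl was -1.002 in arterial-like cells and Tfrc -0.70 in arterial-like and -1.02 in capillary-like cells: 1 more cell redrew the segments, so segment values depend on the clustering. At sub-cluster resolution 0.3, Alpl was -0.27 and Tfrc -0.75 in capillary-like cells, and Tfrc reversed to 0.20 in venous-like cells, where the cluster so named held 28 and 2142 cells. At resolution 1.2, Alpl was -0.89 and Tfrc -0.75 in arterial-like, and -1.001 and -0.91 in capillary-like cells. With the libraries clustered separately, Alpl was -0.83, -1.17 and -2.78 and Tfrc -0.74, -0.91 and -1.92 in arterial-like, capillary-like and venous-like cells. With sub-clusters weighted equally Alpl was -0.62; in shared sub-clusters it was -0.40, with 12 of the 24 named genes chosen again. From a minimum of 20 CPM, 10 of the 24 were chosen, since more genes compete. The caveolae median was -0.11 without a CPM minimum, -0.36 from 50 CPM, -0.0293 without the Plvap-led sub-cluster, which holds nearly all Plvap, and 0.0218 in shared sub-clusters. For the caveolae median and the other values the cause was not tested. In venous-like cells Alpl rested on 33 and 14 UMIs from 236 and 268 cells, so the number of cells and the low level of Alpl limit it; the median of 4549.5 UMIs per cell there was above those of both capillary-like sub-clusters (3997 and 3777).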

Other observations

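The circadian test below was chosen after its result had been seen, whereas the interferon-gamma and glucocorticoid tests were written before any ratio of their lists' genes had been seen, although a few of these, such as Iigp1 and Mt1, had appeared among the genes that lead clusters. Directions follow the sample titles, which the file names contradict.

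Several lists had other medians in venous-like cells (236 and 268) than in other segments, with more counting error. Nutrient transporters of the barrier had 11 of 19 members lower and 4 higher in the library labelled ALPL there, with a median log2 ratio of -0.45 at percentile 0, against -0.11 in arterial-like and -0.25 in capillary-like cells. The type I interferon list had 11 of 20 members lower in venous-like cells, with a median of -0.41, and went the same way in capillary-like cells, with -0.11 at percentile 0.85, against 0.12 in arterial-like cells at percentile 99.92. The capillary-like cells of the libraries lay mostly in different sub-clusters. Over the sub-clusters shared by both libraries the median of this list was 0.38, so its capillary-like direction is open. Immediate early genes had 16 of 18 members higher and 0 lower in venous-like cells, with medians of 0.05, 0.55 and 0.76 from arterial-like to capillary-like to venous-like. Iron handling had medians of -0.02, 0.12 and 0.48, and the unfolded protein and integrated stress response 0.11, -0.03 and 0.27, in the same order. Caveolae and vesicles of non-selective uptake had 7 of 11 members lower there, with a median of -0.49, against -0.00 and 0.04 in arterial-like and capillary-like cells. These differences between segments were not tested.

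As a hypothesis, the lower antigen presentation genes, Gbp4, Igtp and Irgm1 may belong to a lower interferon-gamma response in the library labelled ALPL. A list of 21 other interferon-gamma genes was drawn up, of which 12 were measured. Of these 10 were lower by the preset fold bound and 0 higher, with a median of -0.53 at percentile 0, which is what the hypothesis needs. The guanylate-binding proteins Gbp2 and Gbp3 stood at -0.79 and -0.75, the GTPases Irgm2 and Iigp1 at -0.78 and -0.68, Tgtp2 at -1.04 and the proteasome activator Psme1 at -0.20. Some of these genes are also induced by type I interferon. Clusters led by interferon-induced genes held more cells labelled ALPL, however. A cluster led by Ifit1, Isg15, Ifit3 and Iigp1 held 87 and 204 cells. At sub-cluster resolution 1.2, 1 with Isg15, Iigp1 and Gbp7 among its leading genes held 113 and 364. This list was summarised over the whole class only. In shared sub-clusters the antigen presentation median was -0.28 and the type I interferon median 0.38, so a lower interferon response in general is not shown.

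A second hypothesis was that Cdkn1a, Map3k6 (log2 ratio 2.66, at a mean of 36.7 CPM) and Cebpd may be higher through a stronger glucocorticoid response. The list drawn up for it left out glucocorticoid-response genes that had already been seen. Of its 14 genes 11 were measured, with 5 higher, 2 lower and a median of 0.24 at percentile 99.99. Ddit4, Angptl4 and Rhob stood at 0.76, 0.63 and 0.50 and Klf9 at 0.24, but Mt1 and Cdkn1c stood at -0.36 and -0.49, so the list went both ways and the test is a weak one.

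The lower Dbp raised the hypothesis that the pools may have been collected at different times of day. Of 7 other circadian output genes 5 were measured, with 3 lower, 0 higher and a median of -0.426 at percentile 0.01. With Dbp included the median was -0.48 at percentile 0, but Dbp prompted the hypothesis, so this is no separate support. Dbp itself ran from -1.09 to -0.56 over the alternatives. Per3 stood at -0.67, Nr1d1 at -0.53, Tef at -0.43, and Nr1d2 and Hlf at -0.18 and -0.16. The hour of collection was not given in the sources used here.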
